A study of Mus musculus with 48 samples.

How the data were processed

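The 5′ ends of capped RNA were counted (CAGE, cap analysis of gene expression) in 48 mouse libraries from total RNA of T cells. Of these, 26 came from the DO11.10 T hybridoma, a T cell line whose receptor recognises an ovalbumin peptide (pOVA), and 22 from primary CD4+ T cells of BALB/c mice stimulated with 2C11, an antibody to CD3. Both systems were stimulated in a dose series with or without engagement of PD-1, an inhibitory receptor. The labels do not give the way PD-1 was engaged, the time of stimulation, or whether replicates were separate cultures or animals. The p-values below therefore measure the spread between these samples.

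The deposited table of each system gives 1 value per tag cluster (a short stretch of transcription start sites on 1 strand) and library, in RPM as made by the authors, that is, tags scaled to the total of the library. The low values of every library were whole multiples of 1 step, and with that step 100% of the values were whole tags within 0.1 tag. The library totals recovered in this way were larger than the sum over the deposited clusters, which held 91.0 to 92.3% of the hybridoma totals and 81.8 to 87.1% of the CD4 totals. Per the submitters' processing notes, BWA 0.7.12, HISAT2 2.0.5 and the mouse build mm9 were used, and the role of each tool is not given in the sources used here. How clusters were called and given gene symbols is not stated. No deposited cluster stayed below 3.00 RPM in all libraries of its system, so genes of low abundance can be missing. No mm9 annotation was used here. Coordinates are printed as deposited (whether counted from 0 or 1 is not stated), and a newer mouse annotation served for symbols and transcript lengths alone.

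The hybridoma table held 18025 clusters, of which 4477 carried no gene symbol and 356 carried more than 1. The CD4 table held 17272 clusters, with 3643 and 371 of these kinds. Values were summed per gene symbol over clusters with a single symbol, which gave 10098 and 10219 genes, and 9060 and 9164 of these symbols occur in the reference annotation. In the 2 tables, 16 and 13 symbols had been turned into calendar dates and were kept as they stood. Clusters with no symbol were tested apart from the genes.

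Library totals ranged from 7.79 to 19.7 M tags in the hybridoma (median 14.7) and from 4.42 to 22.8 M in CD4 cells (median 10.2). At the smallest total, 1 tag is worth less than 1 RPM, and counting error is largest for genes near the floor. The 10 most abundant genes took 6.33 to 8.65% of the tags of named genes in the hybridoma and 6.53 to 8.78% in CD4 cells. No pair of libraries was a copy of another.

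Each system was fitted apart with limma 3.58.1 (trend, R 4.3.3) on log2(RPM + 1), with 1 mean per group of dose and engagement. All libraries of a system shared 1 estimate of the spread, since most groups held 2 libraries and the top-dose groups 3. Genes with at least 1 RPM in at least 2 libraries were tested, 10094 in the hybridoma and 10217 in CD4 cells. P-values were two-sided and adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change. Errors of log2 differences are standard errors (SE) from this fit, and levels are means with their standard deviation (SD).

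The comparisons were stimulation without engagement (each dose against dose 0, the top dose as the main one), PD-1 engagement (the mean over stimulated doses of engaged minus unengaged as the main one, and each dose), and the difference between the engagement effect under stimulation and at dose 0. For genes at least 2-fold higher at the top dose, the half-maximal dose was read from the unengaged dose curve by interpolation on log10 dose. The inhibition by PD-1 engagement was the percent lost of the rise above dose 0, summed over stimulated doses. Overlap of calls between systems was described with Fisher's exact test, and differences between systems were tested in a joint limma fit.

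The comparisons, the alternatives marked as planned, 21 gene lists (4 of them controls with markers of T cells and of other cell types) and the rule for named genes were fixed before the data were examined. For each of the 4 main contrasts the rule names the 10 higher and the 10 lower called genes with the largest change among genes of at least median abundance, without predicted gene models. It requires no overlap between the libraries of the groups for stimulation, and the same sign at every stimulated dose for PD-1. It adds up to 4 members of each list by size of change, and 8 genes in any case (Il2, Ifng, Egr2, Nr4a1, Myc, Cd69, Pdcd1 and Cd274). Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 42 tests per system, and again with an estimated correlation.

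In the hybridoma, engaged and unengaged libraries of the same dose and replicate number resembled each other. The correlation of their deviations from the group mean was 0.759 at dose 0, 0.256 at 1 nM, 0.405 at 10 nM, 0.325 at 100 nM, 0.407 at 1000 nM, and 0.327, 0.455 and 0.339 at 10000 nM, all above the threshold of 0.1 used for pairing. Values with pairs as a term of the fit (pair-blocked) therefore stand beside the total, list and overlap counts of the averaged PD-1 comparison in the hybridoma where they change them. In CD4 cells most of these correlations were below 0.1 (0.0129 to 0.255), and the numbers were not taken as pairs. Unengaged hybridoma libraries of the same number at different doses, which are not pairs, correlated from -0.363 to 0.329. The threshold of 0.1 alone therefore does not mark a pair.

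The alternatives were quantile normalization, limma without trend, no filter, pseudocounts of 0.1 and 5, replicate number as a factor, the groups of the contrast alone, a 2-fold minimum, a test per cluster, edgeR 4.0.16 on recovered tags with library totals, and leaving out each replicate. For lists, they were an estimated correlation and the fry test. Added after the data were seen were edgeR with TMM factors, DESeq2 1.42.0, TMM-scaled values in limma, a covariate with the mean log2 level of 5 B cell markers, pairs within dose, a fit without both dose 0 hybridoma libraries of number 2, and 1 nM as the baseline. Quantile normalization of the list counts and of the overlap between systems was also added then.

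The procedure was tested on simulated data, with tags drawn from a negative binomial distribution at the mean, spread and library totals of the real genes and 200 genes changed. At a true 2-fold change, 67.2% of changed genes were called for stimulation and 97.0% for the averaged PD-1 contrast in the hybridoma, and 82.1% and 97.0% in CD4 cells. At 1.5-fold these shares were 22.4, 76.1, 43.3 and 88.1%. Unchanged genes made up 3.55 to 6.33% of calls. Tables were handled and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.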

Results

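Transcription start activity was measured in 48 libraries in 22 groups, 12 of the DO11.10 hybridoma and 10 of primary CD4+ T cells. The hybridoma received pOVA at 0, 1, 10, 100, 1000 and 10000 nM, and the CD4 cells 2C11 at 0, 10, 100, 1000 and 10000 ng/ml, each with and without PD-1 engagement. Every group held 2 libraries except the 10000 groups, which held 3. Totals ranged from 7.79 to 19.7 M tags in the hybridoma and from 4.42 to 22.8 M in CD4 cells. The first principal component of log2 levels held 42.5% of the variance in the hybridoma and 68.3% in CD4 cells.

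The series combines TCR stimulation with PD-1 engagement, and the first comparison gives the response of the hybridoma to antigen alone, 10000 nM pOVA against dose 0 without engagement. Transcription factors of the early TCR response rose steeply. Egr2, a zinc finger factor of that response (mm9 chromosome 10, 67000614 to 67000617, plus strand), went from 2.08 ± 0.0566 RPM (mean ± SD, n = 2) to 280.1 ± 39.3 RPM (n = 3). Nr4a1, an orphan nuclear receptor induced by TCR signals (chromosome 15, 101097276 to 101097283, plus strand), rose 40.2-fold (log2 difference 5.33, SE 0.24) to 1454 ± 106 RPM. The chemokine gene Ccl1 (chromosome 11, 81993313 to 81993316, minus strand) rose 562-fold (log2 difference 9.13, SE 0.47, adjusted p = 5.67e-11 with limma), to 1922 ± 237 RPM. Il2, which encodes the T cell growth factor IL-2 (chromosome 3, 37024876 to 37024878, minus strand), was listed at 0 in both dose 0 libraries and reached 9.11 ± 1.23 RPM.

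Of the 15 immediate early and TCR-induced transcription factors measured in the hybridoma, 13 rose and none fell (14 and 0 adjusted over the list alone), among them Egr2 by 6.503, Egr3 by 6.48 and Egr1 by 5.73 on the log2 scale. Myc, a driver of cell growth, did not pass (0.32, SE 0.16, adjusted p = 0.127), although edgeR with TMM factors called it (adjusted p = 0.0262). All 4 chemokines measured rose (3 with the B cell marker covariate), Xcl1 by 3.90, Cxcl10 by 2.02 and Ccl5, near the threshold, by 0.81 (adjusted p = 0.049, 0.0889 with that covariate, 0.0726 with replicate number as a factor). Of 9 cytokines 8 rose and 1 fell, with Tnf at 2.90 and Tnfsf11, the ligand RANKL, at 2.57. Among 13 activation surface molecules 9 rose and none fell, including the death ligand Fasl (6.11) and the costimulatory receptor Tnfrsf9 (5.29). Inhibitory receptors and their ligands rose as well, 5 of 7 with none lower: Cd274, which encodes PD-L1, by 3.43 (SE 0.38), Cd160 by 2.48, Tigit by 2.46, and Pdcd1, which encodes PD-1 itself, by 1.85. Counts over the list alone were the same for these 4 lists, and camera called all 5 lists higher than other genes (adjusted p from 2.00e-26 to 1.98e-06; with an estimated correlation from 5.45e-05 to 0.00251).

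Regulators of the signal itself were also higher in the stimulated hybridoma. Of 16 feedback regulators 9 rose and 3 fell (the same over the list alone; 10 and 1 with quantile normalization), with the cytokine signalling inhibitor Socs1 at 3.52 and the phosphatase genes Dusp4 and Dusp2 at 2.68 and 2.57. Camera gave an adjusted p = 9.40e-06, and an adjusted p = 0.17 with an estimated correlation. Of 14 NF-kB pathway genes 6 rose and none fell (9 and 1 adjusted over the list alone; 10 and 0 with the B cell marker covariate), such as Nfkbid (2.34) and Rel (2.09), with an adjusted p = 2.57e-06 and an adjusted p = 0.229 with an estimated correlation. Of 13 effector and lineage transcription factors 3 rose and 2 fell (the same over the list alone; 5 and 2 with quantile normalization and with the B cell marker covariate), with Irf4 at 3.16 and Nfatc1 at 1.92 (adjusted p = 0.00883, and an adjusted p = 0.304 with an estimated correlation). Ribosome biogenesis genes moved little in size: 10 of 22 rose and none fell (11 and 0 over the list alone), Rrp9 by 0.64 and Gnl3 by 0.64 (adjusted p = 7.27e-07, and an adjusted p = 0.107 with an estimated correlation). Heat shock genes rose, 5 of 7 with none lower over all genes and over the list alone (3 with quantile normalization and with the B cell marker covariate), Hspa1b by 1.56 (adjusted p = 1.21e-04, and an adjusted p = 0.00332 with an estimated correlation).

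Lower genes in the stimulated hybridoma changed less in size. Tuba8, an alpha-tubulin, fell by 1.93 on the log2 scale (SE 0.20, adjusted p = 6.54e-07), from 81.0 ± 21.3 to 20.3 ± 3.54 RPM. Rcsd1 fell by 1.76, Tnfaip8 at -1.66, Il9r, the IL-9 receptor, at -1.55, and the ETS factor Fli1 at -1.52. Of 22 cell cycle genes 14 fell and none rose (16 and 1 over the list alone; 8 lower with the B cell marker covariate), with E2f1 at -1.04 and Mki67 at -0.78 (adjusted p = 0.0031, and an adjusted p = 0.227 with an estimated correlation). Mki67 lost its call without any of 3 libraries (adjusted p = 0.0604 without dose 0 number 1, 0.11 without dose 0 number 2 and 0.0869 without 10000 nM number 3). The resting and naive T cell genes split, with 4 of 12 higher and 3 lower (the same over the list alone): Tsc22d3 fell by 1.48 and Pik3ip1, a brake on PI3 kinase, stood at -1.45, while Lef1 rose by 1.24. Camera did not call that list (adjusted p = 0.538).

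Other lists in the stimulated hybridoma held members that went both ways. Of 14 apoptosis and growth arrest genes 3 rose and 2 fell (4 and 2 over the list alone; 6 and 2 with quantile normalization, 5 and 2 with the B cell marker covariate), the survival gene Bcl2a1d by 2.33, Gadd45b by 2.19 and the cell cycle inhibitor Cdkn1a by 1.90 among the higher, and Bbc3 at -1.24 (adjusted p = 0.0054, and an adjusted p = 0.303 with an estimated correlation). Of 13 T cell identity genes 4 rose and 2 fell, Cd28 by 1.42 and Zap70 by 1.08 (adjusted p = 0.0189, 0.162 with quantile normalization, and an adjusted p = 0.509 with an estimated correlation). Camera did not call 13 interferon-stimulated genes (3 higher and 4 lower, 4 and 4 over the list alone, adjusted p = 0.538), with Isg15 at 1.85 and Ifit2 at -1.13. Nor did it call 20 cholesterol synthesis genes (5 and 3, adjusted p = 0.0877), 17 glycolysis genes (1 and 2, adjusted p = 0.941) or 15 amino acid and ER stress genes (2 and 3, 1 and 4 with quantile normalization, 1 and 1 with the B cell marker covariate, adjusted p = 0.635). Among these uncalled lists and the resting genes, medians were -0.10 for resting, -0.12 for interferon-stimulated, -0.19 for glycolysis and -0.04 for amino acid genes, while camera, which compares with all other genes, placed each above them. The myeloid marker Cst3 stood at -0.16 (adjusted p = 0.238 with limma; 0.813 with camera) and the cytotoxic marker Gzma rose by 0.67 (adjusted p = 0.00865, 0.178 without dose 0 number 2; 0.0926 with camera), each the 1 gene measured of its list. Counts not given over the list alone were the same there.

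The B cell marker genes moved with dose 0 in the hybridoma. The mean log2 level of 5 B cell markers, among them Cd79a, was 5.55 in dose 0 library number 2 and 5.39 in its engaged counterpart, against 2.19 and 3.47 in number 1 and 1.79 to 3.35 in all other hybridoma libraries. Their median difference between the top dose and dose 0 was -1.10, with none of the 5 called. In the list of 18 B cell and antigen-presenting cell markers, Ighm fell by 1.19 (adjusted p = 5.54e-06) and no other member was called, over all genes or over the list alone (camera adjusted p = 0.219, and 0.0323 with quantile normalization). The gene counts that rest on dose 0, and each gene group given as lower above, share these libraries.

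**Figure D1:**
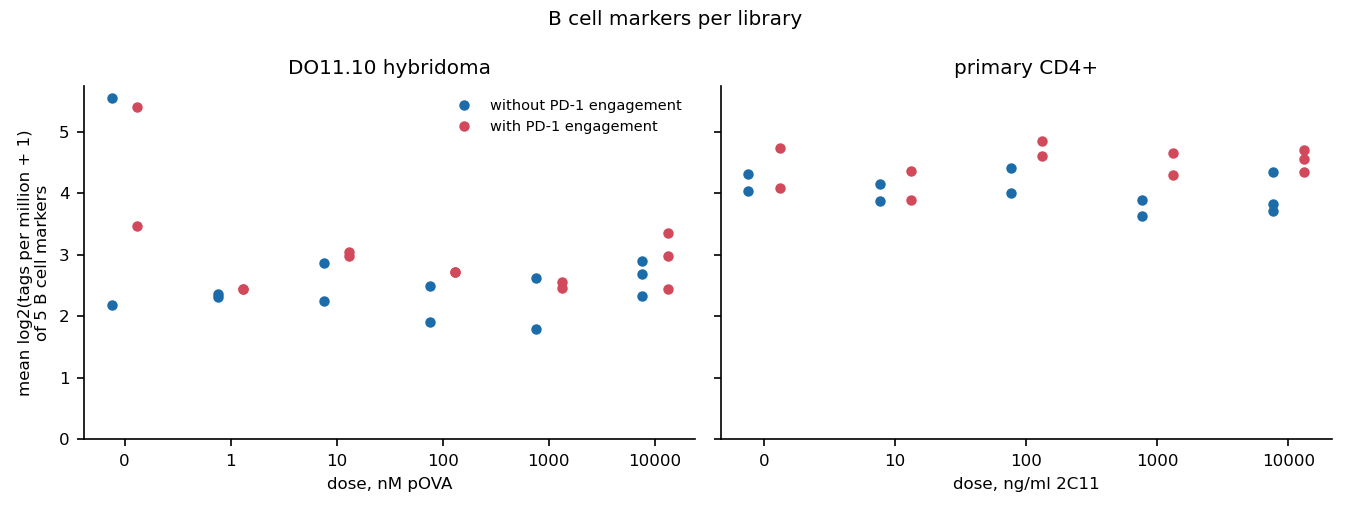
Mean log2 level (RPM + 1) of 5 B cell markers in each library, by system, dose and PD-1 engagement. The dose 0 hybridoma libraries of number 2 stand at 5.55 without and 5.39 with engagement, and all CD4 libraries lie between 3.63 and 4.84.

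In all, 817 genes rose and 2095 fell at 10000 nM, 234 and 267 of them at least 2-fold. Egr1 (2.97, SE 0.40), Egr3 (2.37, SE 0.20) and Egr2 (2.05, SE 0.26) were the 3 genes called at 10 nM, named after their values were seen. At 100 nM 287 genes rose and 322 fell, and at 1000 nM 721 and 2365. The sum was 694 at 10 nM without dose 0 number 1 and 5 without dose 0 number 2. At 100 nM (609 in sum) it was 1307 and 306 without these, 197 without 100 nM number 1 and 230 without 100 nM number 2, and at 1000 nM (3086) 1529 without dose 0 number 2 and 1257 without 1000 nM number 2. At 1 nM limma called 0 genes (1017 at an unadjusted p under 0.05; 0 by edgeR with TMM factors and 36 by DESeq2), and it called 840 without dose 0 number 1, 2 without dose 0 number 2, 3 without 1 nM number 1 and 1 without 1 nM number 2. The median log2 difference of all genes was -0.177 with library totals and -0.0351 with quantile normalization, which called 1300 higher and 1435 lower, of which 731 and 1282 are shared with the counts above. The number lower depended on single libraries: 980 without dose 0 number 2 and 1266 without 10000 nM number 3, and 1001 without both dose 0 libraries of number 2, of which 953 are shared.

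**Figure D2:**
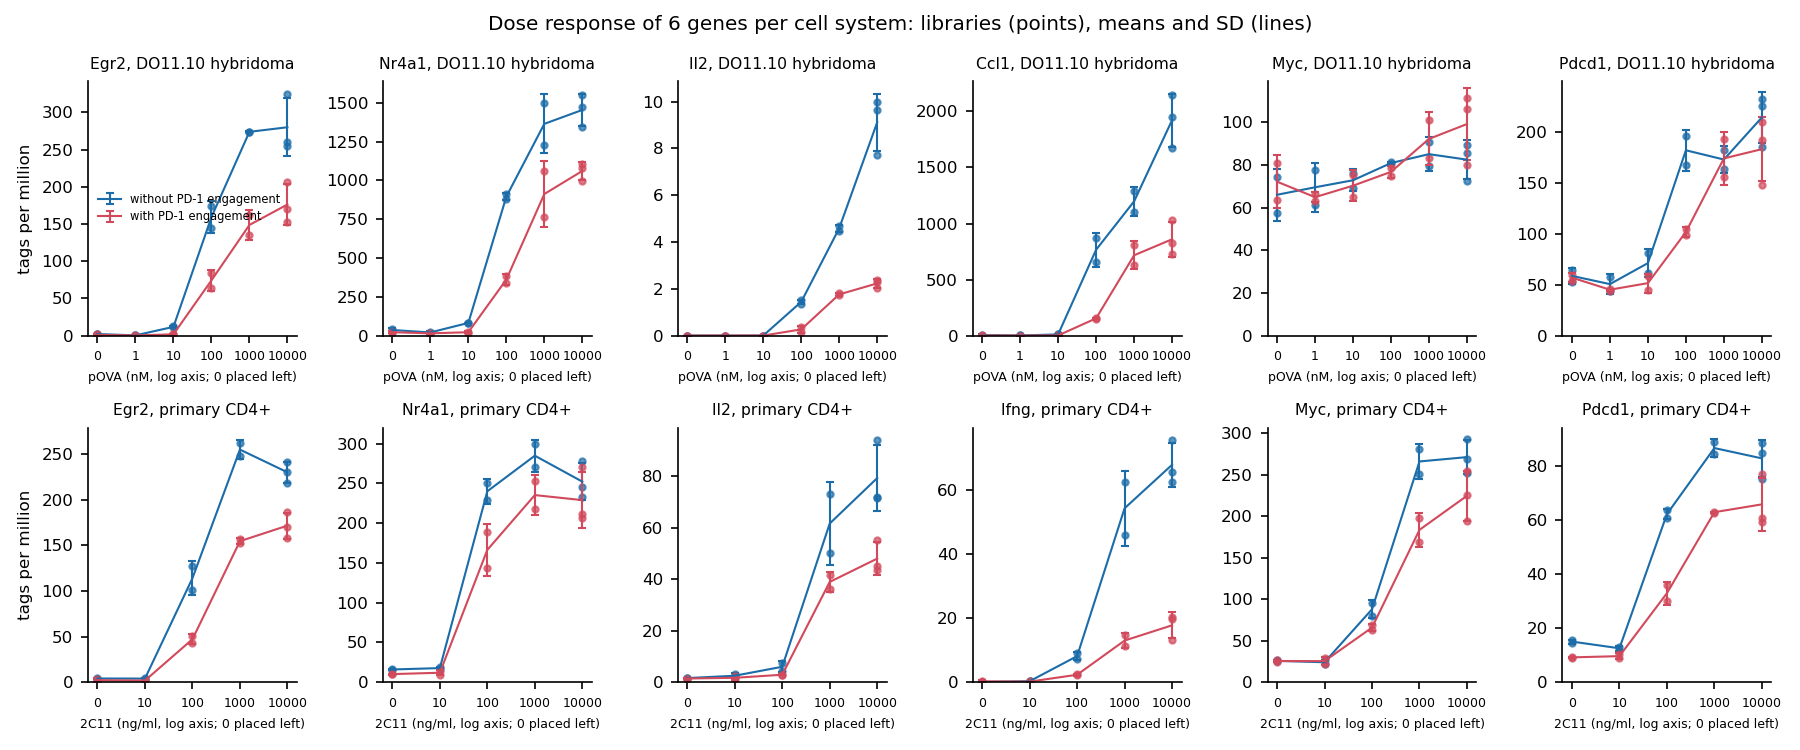
Levels (RPM) of 6 genes per system against dose (log axis), with and without PD-1 engagement; points are libraries, and lines join means with their SD. Hybridoma Egr2 rises from 2.08 RPM at dose 0 to 280.1 RPM at 10000 nM without and 176.2 RPM with engagement.

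The second comparison gives the effect of PD-1 engagement in the hybridoma, averaged over 1 to 10000 nM. Several TCR-induced genes were lower with engagement. Ccl1 was lower by a log2 difference of -1.48 (SE 0.22, adjusted p = 0.00111), at 100 nM 154 ± 3.78 RPM with against 766 ± 151 without (n = 2 each). Egr2 was lower by a log2 difference of -0.999 (SE 0.11, adjusted p = 4.18e-05), with 74.2 ± 14.2 against 159 ± 21.4 RPM at 100 nM and 176 ± 27.8 against 280.1 ± 39.3 RPM at 10000 nM (n = 3 each). Nr4a1 fell by 0.95 (SE 0.11), the AP-1 factor Fosl2 at -0.63, the endosomal tether Eea1 at -0.62, the RNA-binding Zfp36l1 at -0.58 and the calcium channel gene Orai1 at -0.57. Il2 was 2.23 ± 0.183 RPM with and 9.11 ± 1.23 RPM without engagement at 10000 nM (n = 3 each), where its difference was called (adjusted p = 1.0e-05 with limma).

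Among the fixed lists, 6 of 15 immediate early transcription factors fell with engagement in the hybridoma and none rose (11 and 0 adjusted over the list alone; 12 and 0 pair-blocked), Nr4a3 at -0.825 and Egr3 at -0.81. Cytokines fell, 4 of 9 with none higher (6 and 0 over the list alone; 5 and 0 pair-blocked), among them Tnf at -0.46 and Tnfsf11 at -0.46. Chemokines fell, 2 of 4 with none higher (the same over the list alone), with Xcl1 at -1.11 beside Ccl1. Of 13 activation surface molecules 3 fell and none rose (8 and 0 over the list alone and pair-blocked; 6 and 0 with the B cell marker covariate), Fasl at -0.93 and Tnfrsf9 at -0.755. Of 7 inhibitory receptors 2 fell and none rose (3 and 0 over the list alone; 4 and 0 pair-blocked), Tigit at -0.55 and Cd160 at -0.52. Camera called these 5 lists lower (adjusted p from 1.47e-24 to 3.57e-07; with an estimated correlation from 5.45e-05 to 0.00153). Of 16 feedback regulators 4 fell and none rose (6 and 1 over the list alone; 8 and 1 pair-blocked), such as Spry1 at -0.60 (adjusted p = 2.55e-06, and an adjusted p = 0.151 with an estimated correlation). Of 14 NF-kB pathway genes 1 fell and none rose (4 and 1 over the list alone; 5 and 1 pair-blocked; 5 and 0 with the B cell marker covariate), with an adjusted p = 0.0176 and an adjusted p = 0.606 with an estimated correlation. Irf4, a factor needed for effector differentiation, fell by 0.72 as 1 of 2 lower among 13 effector factors (2 lower and 1 higher over the list alone; 4 and 2 pair-blocked), a list that camera did not call (adjusted p = 0.0833, and 0.0401 with quantile normalization).

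Without pairs, few genes rose with engagement (6; 201 pair-blocked). The 6 genes higher with engagement in the hybridoma, most of them named after their values were seen, were Cd200r1 (0.41, SE 0.07), Tsc22d3 (0.38, SE 0.09), Il16 (0.34), St8sia4 (0.26), Tnfaip8 (0.25) and the histone gene Hist1h4n (0.19, SE 0.04). All 6 had fallen with stimulation, Il16 at -2.18, Cd200r1 at -1.97, Tnfaip8 at -1.66, St8sia4 at -1.504, Tsc22d3 at -1.48 and Hist1h4n at -0.74. Unengaged libraries enter both contrasts with opposite sign, and unrelated lists would share 1.25 genes of this kind. The number higher with engagement was 3 without 100 nM number 2 and 3 without engaged 10 nM number 1. Hist1h4n and Tsc22d3 lost the call with quantile normalization (adjusted p = 0.353 and 0.0841). Of the 12 resting and naive genes, Tsc22d3 was the 1 called without pairs (2 higher and 1 lower over the list alone; 2 and 2 pair-blocked and with the B cell marker covariate), and camera did not call the list (adjusted p = 0.941).

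Cd274 (-0.41, adjusted p = 0.798), Cd69 (-0.24, adjusted p = 0.113) and Pdcd1 (-0.33, adjusted p = 0.0597) did not pass in the hybridoma without pairs, and passed in the pair-blocked fit (adjusted p = 1.46e-04, 0.00867 and 3.60e-05). Myc stood at 0.03 (SE 0.07, adjusted p = 1). The ribosome biogenesis list had no member called of 22 over all genes or over the list alone (2 lower pair-blocked), and camera gave an adjusted p = 0.0461 (0.0547 pair-blocked, 0.264 with quantile normalization, and an adjusted p = 0.555 with an estimated correlation). The B cell and antigen-presenting cell markers were higher as a set beside these groups (median 0.28, adjusted p = 0.00302, and an adjusted p = 0.615 with an estimated correlation), with none of 18 called over all genes or over the list alone.

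Several metabolic, cell cycle and stress lists showed no member called with engagement in the hybridoma without pairs: 20 cholesterol synthesis genes (Dhcr7 0.17; camera adjusted p = 0.555), 17 glycolysis genes (Slc2a1 -0.11; 0.716), 22 cell cycle genes (Ccnd2 -0.15; 0.732), 13 interferon-stimulated genes (Isg15 -0.26; 0.716), 14 apoptosis and growth arrest genes (Bcl2a1d -0.30; 0.725), 7 heat shock genes (Hspa1b -0.17; 0.0833), 15 amino acid and ER stress genes (Phgdh 0.17; 0.607) and 13 T cell identity genes (Zap70 -0.24; 0.941). Over the list alone 1 apoptosis gene was lower, and counts were otherwise the same. Pair-blocked, 2 cholesterol synthesis, 2 apoptosis, 1 interferon-stimulated and 1 heat shock gene were lower, 2 amino acid genes higher and 1 lower, and 3 T cell identity genes higher and 1 lower. Cst3 stood at 0.06 (camera adjusted p = 0.371) and Gzma at -0.02 (0.907). Median, mean and camera differed in sign for interferon-stimulated genes (0.00273, -0.03 and below other genes), T cell identity genes (0.02, -0.02 and below) and resting genes (-0.05, -0.02 and above).

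In all, 88 genes fell and 6 rose with engagement in the hybridoma. With pairs blocked 456 fell and 201 rose, including all 88 and all 6, and by single dose limma called 0 at 1 nM, 4 at 10 nM, 50 at 100 nM, 8 at 1000 nM and 41 at 10000 nM, against 4, 15, 426, 741 and 254 with pairs blocked. The balance turned at 1000 nM, from 1 higher and 7 lower to 537 higher and 204 lower pair-blocked. At 100 nM it was 46 higher and 380 lower pair-blocked, and at 10000 nM 93 and 161. The 4 called at 10 nM all fell: Egr2 (-2.24), Nr4a1 (-1.90), Egr3 (-1.66) and Tnfrsf9 (-1.27). At dose 0 limma called 0 genes (68 at an unadjusted p under 0.05; 0 with pairs blocked, with edgeR and with DESeq2), and at 1 nM the 0 stands beside 58 at an unadjusted p under 0.05, 0 by edgeR and 6 by DESeq2. Genes at or near 0 RPM at low doses lost their averaged call with edgeR on recovered tags: Il2 (adjusted p = 1), Il3 (1), Fasl (1), Xcl1 (0.249), Cd160 (1) and Spry1 (0.148). Leaving out 1 library changed the counts at single doses. That at 10 nM was 2 without 10 nM number 2, and that at 1000 nM 4 without 1000 nM number 1 and 1 without engaged number 2. That at 100 nM was 11 and 20 without unengaged numbers 1 and 2, and 18 and 32 without engaged numbers 1 and 2. That at 10000 nM was 18, 24 and 18 without unengaged numbers 1, 2 and 3, and 21 and 13 without engaged numbers 2 and 3. That at dose 0 was 2 without unengaged number 1, 3 without unengaged number 2 and 2 without engaged number 2, and that at 1 nM 5, 1 and 1 without the same libraries of its dose. The number called at any dose, 75, was 40 without 100 nM number 1, 46 without 100 nM number 2 and 49 without the engaged 10000 nM library of number 2.

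**Figure D3:**
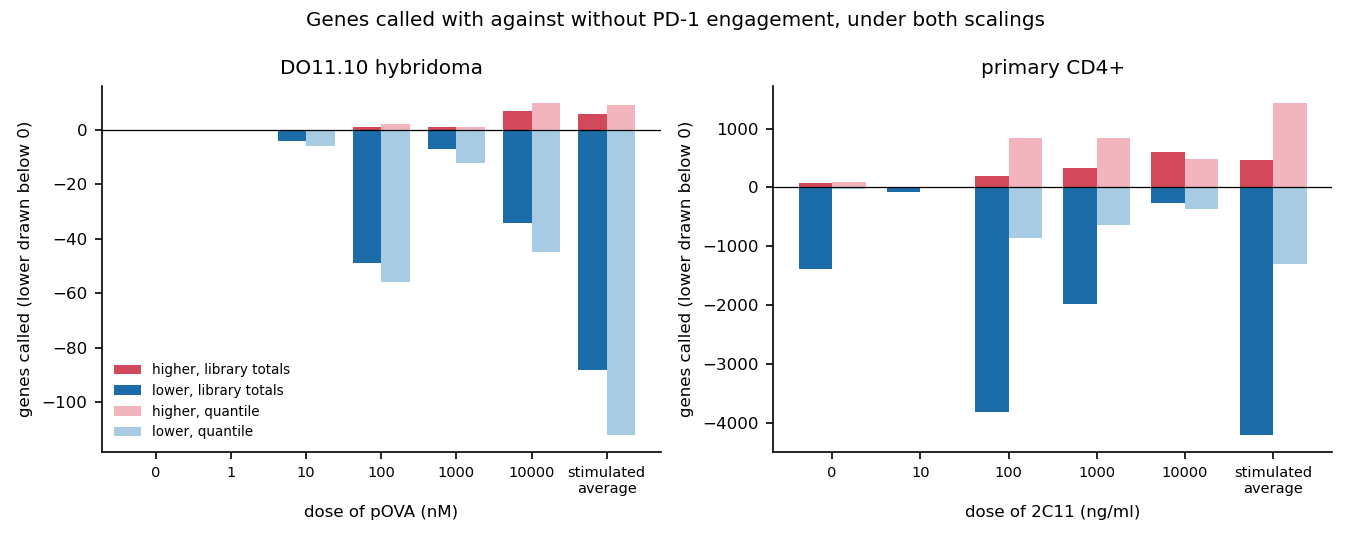
Genes called higher and lower with PD-1 engagement at each dose and averaged over stimulated doses (adjusted p under 0.05 with limma), by system, with scaling to library totals and with quantile normalization. The averaged counts are 6 higher and 88 lower in the hybridoma and 458 higher and 4205 lower in CD4 cells.

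No gene passed the test of a difference between the engagement effect under stimulation and at dose 0 in the hybridoma (0 with limma, 110 at an unadjusted p under 0.05, 0 by edgeR and DESeq2, 7 with pairs blocked; 3 without dose 0 number 1, 1 without engaged dose 0 number 2 and 1 without engaged 100 nM number 1). For Egr2 that difference was -0.21 (SE 0.28) and for Xcl1 -0.88 (SE 0.21).

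Among genes at least 2-fold higher in the stimulated hybridoma (234), those that needed more antigen lost more to PD-1 engagement. The median half-maximal dose was 94.0 nM (quartiles 51.2 and 201 nM), and the median inhibition 40.0% (quartiles 28.4 and 54.5%). In the 78 genes with the lowest half-maximal dose (median 44.1 nM) the median inhibition was 32.2%, in the middle 78 (94.0 nM) 37.8%, and in the 78 highest (287 nM) 55.3%. Spearman's rho across genes was 0.51, and genes are not independent replicates. With the dose taken from 1 replicate number and the inhibition from the other it was 0.47 and 0.38, without number 1 it was 0.337 and without number 2 0.308. Of the 234 genes 226 had a negative averaged engagement difference and 75 were called lower. Over all genes, 84 rose with stimulation and fell with engagement (7.12 for unrelated lists). Both contrasts share unengaged libraries. Without an engagement effect, 20 simulations that kept these and the stimulation differences gave 0.05 such genes on average and 1 at most. Hardly any gene is called with engagement in such simulations, so this cannot tell how far the shared libraries raise the overlap. The Spearman correlation of stimulation and engagement differences across genes was -0.507, against -0.0596 on average in the simulations.

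**Figure D4:**
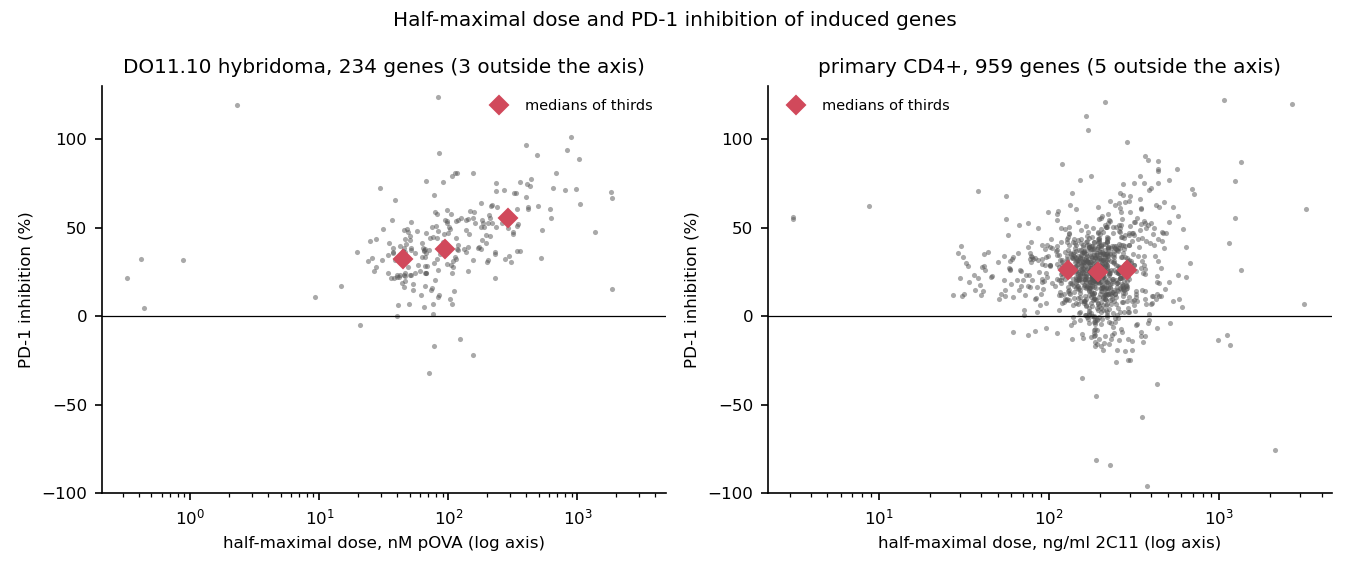
Inhibition by PD-1 engagement (percent of the rise lost, summed over stimulated doses) against the half-maximal dose of each induced gene (log axis), by system; diamonds are medians of 3 groups of genes ordered by that dose. The Spearman correlation across genes is 0.51 over 234 hybridoma genes and 0.06 over 959 CD4 genes.

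Primary CD4 cells answered 2C11 with higher cytokine and immediate early genes and lower genes of the resting state, in the comparison of 10000 ng/ml with dose 0 without engagement. Crabp2, a retinoic acid binding protein (chromosome 3, 87752615 to 87752619, plus strand), rose from 1.09 ± 0.888 RPM (n = 2) to 393 ± 34.0 RPM (n = 3), a log2 difference of 7.62 (SE 0.19, adjusted p = 2.59e-16). Il4, a cytokine of type 2 helper cells (chromosome 11, 53432166 to 53432169, minus strand), went from 3.42 ± 0.619 to 432 ± 53.2 RPM, and Ifng, the cytokine of type 1 cells (chromosome 10, 117878101 to 117878102, plus strand), from 0.0355 ± 0.0502 to 68.0 ± 6.84 RPM. Myc rose from 25.6 ± 0.819 to 271 ± 20.3 RPM, and Egr2 from 3.94 ± 0.384 to 230.2 ± 11.6 RPM. S1pr1, which lets T cells leave lymph nodes (chromosome 3, 115417711 to 115417859, minus strand), fell from 266 ± 3.61 to 12.2 ± 0.698 RPM.

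All 22 ribosome biogenesis genes rose in CD4 cells, Gnl3 by 2.82 and Rrp9 by 2.66 (adjusted p = 1.66e-13 with camera, and an adjusted p = 0.113 with an estimated correlation). Of 16 cytokines 15 rose and none fell, Lif by 5.63, Csf2 by 4.98 and Il2 by 4.96 (SE 0.22). Of 6 chemokines 4 rose and none fell, Ccl1 by 6.64, Ccl4 by 6.48 and Ccl3 by 5.75. Of 18 immediate early transcription factors 17 rose and 1 fell, Nr4a3 by 5.12 and Fosl1 by 4.80. These 3 lists were called with an estimated correlation too (adjusted p = 0.0324 for each), and counts over the list alone were the same for them and for ribosome biogenesis. Of 16 activation surface molecules 13 rose and 2 fell (14 and 2 over the list alone), Tnfsf14 by 4.07 and Cd40lg by 3.11 (adjusted p = 7.04e-08, and an adjusted p = 0.0528 with an estimated correlation). Of 11 inhibitory receptors 7 rose and 3 fell (the same over the list alone), Cd160 by 2.91, Havcr2 by 2.73 and Pdcd1 by 2.39 (adjusted p = 0.0152, and an adjusted p = 0.2 with an estimated correlation). Feedback regulators went both ways, 12 of 18 higher and 4 lower (the same over the list alone), with Spry1 at 4.87 and the diacylglycerol kinase Dgka at -2.15 (adjusted p = 0.00209, and an adjusted p = 0.0493 with an estimated correlation). Of 16 effector and lineage transcription factors 10 rose and 5 fell (the same over the list alone), Nfil3 by 2.32 and Irf4 by 2.06 (adjusted p = 0.00967, and an adjusted p = 0.266 with an estimated correlation).

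Metabolic and stress genes rose in part of each list in CD4 cells. Of 18 glycolysis genes 10 rose and 3 fell (10 and 4 over the list alone), the hexokinase gene Hk2 by 2.10 and the lactate transporter gene Slc16a1 by 2.02 (adjusted p = 0.0103, and an adjusted p = 0.351 with an estimated correlation). Heat shock genes rose, 5 of 8 with none lower (the same over the list alone), Hspd1 by 2.04 and Hsph1 by 1.81 (adjusted p = 0.00452, and an adjusted p = 0.0681 with an estimated correlation). Of 14 amino acid and ER stress genes 11 rose and 3 fell (the same over the list alone), with Shmt2, a serine metabolism enzyme, at 1.17 and Trib3 at -2.02 (adjusted p = 0.0155, and an adjusted p = 0.266 with an estimated correlation). All 18 resting and naive T cell genes fell, over all genes and over the list alone, Pik3ip1 at -4.06, Tsc22d3 at -3.92 and Klf2, a factor that keeps T cells quiescent, at -3.58 (adjusted p = 4.26e-09, and an adjusted p = 0.0493 with an estimated correlation). The cell cycle inhibitor gene Cdkn1b fell by 3.65 and Tcf7 at -3.02. The NF-kB list went both ways (6 of 14 higher and 5 lower, the same over the list alone) and was not called (adjusted p = 0.301).

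The remaining lists in stimulated CD4 cells were not called by camera. Interferon-stimulated genes were mostly lower (12 of 17 lower and 2 higher; adjusted p = 0.0544, 0.0403 with quantile normalization and 0.0315 with replicate number as a factor), with Gbp2 at -1.62. Of 22 cell cycle genes 6 rose and 9 fell (adjusted p = 0.734), Ccnd2 at 1.12 and Mki67 at -1.61. Of 14 apoptosis and growth arrest genes 7 rose and 5 fell (7 and 3 with quantile normalization; 0.172), Gadd45g at 2.50 and Bbc3 at -2.51. Of 20 cholesterol synthesis genes 9 rose and 4 fell (0.0743), Hsd17b7 at 1.54, and of 14 T cell identity genes 3 rose and 9 fell (0.514), Lcp2 at 1.54 and Cd4 at -0.84. Of 17 B cell and antigen-presenting cell markers 3 rose and 1 fell (2 and 1 over the list alone; 9 and 1 with the B cell marker covariate; 0.686), Cd40 at 1.40 and Ighm at -2.10. Cst3 stood at -0.14 (adjusted p = 0.0696; called over the list alone; 0.787 with camera). Of 4 cytotoxic markers 1 rose, Nkg7 by 2.40, and 1 fell, Gzma at -0.40 (adjusted p = 0.0391, 0.472 with quantile normalization; not called over the list alone), with a median of -0.12, a mean of 0.44 and a camera test above other genes (0.622). Counts not given over the list alone were the same there.

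In all, 2812 CD4 genes rose and 4101 fell, 959 and 1477 of them at least 2-fold. At 10 ng/ml limma called 0 genes (425 at an unadjusted p under 0.05; 0 by edgeR and 3 by DESeq2; 2 without dose 0 number 2 and 6 without 10 ng/ml number 2), at 100 ng/ml 1964 rose and 737 fell, and at 1000 ng/ml 3178 and 3052. Quantile normalization, against a median shift of -0.152, called 3278 higher and 3506 lower, of which 2727 and 3411 are shared. The sum of 2701 calls at 100 ng/ml was 1582 without dose 0 number 1, 1594 without dose 0 number 2 and 1273 without 100 ng/ml number 2.

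PD-1 engagement in CD4 cells, averaged over 10 to 10000 ng/ml, lowered cytokine and chemokine genes most in size. Ifng was 17.8 ± 4.08 RPM with and 68.0 ± 6.84 RPM without engagement at 10000 ng/ml (n = 3 each; averaged log2 difference -1.38, SE 0.11, adjusted p = 9.17e-08). Il4 was 174 ± 36.1 against 432 ± 53.2 RPM (averaged -1.16, SE 0.11), Ccl1 52.7 ± 4.86 against 147 ± 13.4 RPM (averaged -1.41, SE 0.08), and Crabp2 246 ± 30.8 against 393 ± 34.0 RPM. The protease gene Furin fell by 0.92, the semaphorin Sema7a at -0.83, Egr2 at -0.81 (SE 0.13, adjusted p = 1.35e-04), Spry1 at -0.77 and Rgs16 at -0.76. Il2 fell by 0.63, Pdcd1 at -0.51, Cd274 at -0.41, Cd69 at -0.39 and Nr4a1 at -0.38. Myc fell by 0.29 (adjusted p = 0.00191) and lost the call with quantile normalization (-0.14, adjusted p = 0.0748).

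The list counts with engagement in CD4 cells stand against 4205 lower and 458 higher among all 10217 genes tested. All 16 cytokines fell with engagement in CD4 cells over all genes and over the list alone (15 with quantile normalization), Csf2 at -1.07 beside Ifng and Il4 (adjusted p = 5.73e-10 with camera, and an adjusted p = 0.0324 with an estimated correlation). Of 18 feedback regulators 14 fell and none rose (15 and 0 over the list alone), such as Cish at -0.65 (adjusted p = 1.33e-04, and an adjusted p = 0.0324 with an estimated correlation). Of 18 immediate early transcription factors 13 fell and none rose (15 and 0 over the list alone; 10 with quantile normalization), Nr4a3 at -0.77 and Fosl1 at -0.71 (adjusted p = 1.62e-04, and an adjusted p = 0.125 with an estimated correlation). Chemokines fell, 4 of 6 with none higher (the same over the list alone), Ccl3 at -1.38 (adjusted p = 0.0259, 0.0677 with replicate number as a factor, 0.13 with pairs, and an adjusted p = 0.113 with an estimated correlation). Of 16 activation surface molecules 14 fell and none rose (the same over the list alone; 9 with quantile normalization), Tnfsf8 at -0.65 and Tnfsf14 at -0.64 (adjusted p = 2.49e-04, and an adjusted p = 0.17 with an estimated correlation). Of 11 inhibitory receptors 7 fell and none rose (8 and 0 over the list alone), Havcr2 at -0.78, a gene near 0 RPM that edgeR did not call (adjusted p = 1), and Cd160 at -0.56 (adjusted p = 0.0141, and an adjusted p = 0.2 with an estimated correlation). All 14 NF-kB pathway genes fell over all genes and over the list alone (9 with quantile normalization), Nfkb1 at -0.59 and Relb at -0.45 (adjusted p = 1.05e-04, and an adjusted p = 0.2 with an estimated correlation). Of 16 effector factors 12 fell and none rose (the same over the list alone), Tbx21, the factor of type 1 helper cells, at -0.64 and Nfil3 at -0.61 (adjusted p = 0.00153, and an adjusted p = 0.2 with an estimated correlation).

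Most genes of the glycolysis, ribosome biogenesis and cholesterol synthesis lists were lower with engagement in CD4 cells, and with an estimated correlation none of these 3 lists was called. Of 18 glycolysis genes 14 fell and none rose (15 and 0 over the list alone; 12 with quantile normalization), Hk2 at -0.70 and Slc16a3 at -0.57 (adjusted p = 1.54e-04, and an adjusted p = 0.196 with an estimated correlation). Of 22 ribosome biogenesis genes 20 fell and none rose (the same over the list alone; 10 with quantile normalization), Nolc1 at -0.41 and Polr1b at -0.40 (adjusted p = 0.00103, and an adjusted p = 0.445 with an estimated correlation). Of 20 cholesterol synthesis genes 13 fell and none rose (the same over the list alone; 5 lower and 2 higher with quantile normalization), Insig1 at -0.42 (adjusted p = 0.0336, 0.196 with quantile normalization, 0.0531 with pairs, and an adjusted p = 0.445 with an estimated correlation). The resting and naive list split, 4 of 18 higher and 6 lower (the same over the list alone; 8 higher and 0 lower with quantile normalization, 4 and 3 with the B cell marker covariate), and camera placed it above other genes (adjusted p = 0.00355, and an adjusted p = 0.258 with an estimated correlation). Its members Klf2 (0.25), Txnip (0.25) and S1pr1 (0.24) rose, and Klf2 lost its call without engaged 100 ng/ml number 1 (adjusted p = 0.0546) or engaged 1000 ng/ml number 1 (0.0554).

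Among all 10217 genes tested, 90.2% of the calls with engagement in CD4 cells were lower. Camera did not call the remaining lists, and most of their called members were lower too. These were 13 lower of 22 cell cycle genes (13 lower and 1 higher over the list alone; 3 lower and 5 higher with quantile normalization; adjusted p = 0.385; E2f1 -0.34), 6 of 17 interferon-stimulated genes (5 over the list alone; 1 with quantile normalization; 4 lower and 3 higher with the B cell marker covariate; 0.954; Ifih1 -0.47), 9 lower and 2 higher of 14 apoptosis genes (5 and 3 with quantile normalization, 8 and 0 with that covariate; 0.417; Gadd45g -0.55), and 5 of 8 heat shock genes (3 with quantile normalization; 0.321; Hsph1 -0.41). Of 14 amino acid and ER stress genes 7 fell (8 over the list alone; 3 with quantile normalization; 0.276; Slc7a5 -0.50), and of 14 T cell identity genes 10 fell and 1 rose (11 and 1 over the list alone; 7 and 0 with quantile normalization; 0.085, and 0.00356 with quantile normalization; Zap70 -0.41). Cst3 stood at 0.07 (adjusted p = 0.103, and 5.02e-04 with quantile normalization; 0.143 with camera). Of 4 cytotoxic markers 1 fell, Nkg7 at -0.52 (0.931 with camera). Interferon-stimulated genes had a median of -0.11 and cytotoxic markers of -0.25, while camera placed both above other genes. Counts not given over the list alone were the same there.

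Antigen-presenting and B cell genes rose with engagement in CD4 cells beside all of these groups. Igj, the immunoglobulin J chain (chromosome 5, 88956828 to 88956841, minus strand), was 115 ± 19.5 RPM with and 68.4 ± 15.2 RPM without engagement at 10000 ng/ml (averaged 0.79, SE 0.12, adjusted p = 7.16e-05). The class II genes H2-Eb1, H2-Aa and H2-Ab1 rose by 0.58, 0.57 and 0.46, Cd74 by 0.45, and Cd79a, a chain of the B cell receptor complex (chromosome 7, 25682479 to 25682528, plus strand), by 0.42. Of 17 B cell and antigen-presenting cell markers 12 rose and none fell (the same over the list alone), Cd22 by 0.72 and Igkc by 0.67 (adjusted p = 5.56e-14, and an adjusted p = 0.0528 with an estimated correlation). The mean log2 level of 5 B cell markers was 3.63 to 4.41 in unengaged and 3.89 to 4.84 in engaged CD4 libraries. That mean was used as a covariate, a choice made after the data were seen. The list holds all 5 genes of the covariate, whose own change it removes by construction. Of the other 12 markers 8 were higher without it, and 2 higher and 2 lower with it. With the covariate H2-Eb1 stood at 0.02 (adjusted p = 0.895) and Cd74 at -0.11 (adjusted p = 0.0928), while Ifng and Il4 remained called. Its effect went beyond the markers. Over all genes 308 were higher with it, among them 231 of the 458 higher without it. It called 4687 lower, among them 3559 of the 4205 lower without it.

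In all, 458 CD4 genes rose and 4205 fell with engagement, so 90.2% of calls were lower, against a median shift of all genes of -0.145. The averaged difference correlated across genes with that at dose 0, which comes from other libraries (rho 0.494, and 0.485 with quantile normalization). Part of the averaged difference was therefore also seen without stimulation. With the stimulation difference, which shares unengaged libraries, rho was -0.234. Across 9162 genes the averaged difference went with transcript length (rho -0.398), and the list results with engagement in CD4 cells were not corrected for it. Quantile normalization called 1440 higher and 1301 lower, and both scalings shared 427 higher and 1292 lower genes. At single doses 78 rose and 1389 fell at dose 0, 5 and 72 at 10 ng/ml, 195 and 3808 at 100 ng/ml, 337 and 1978 at 1000 ng/ml, and 602 and 264 at 10000 ng/ml, against 98 and 32, 5 and 2, 842 and 867, 843 and 634, and 481 and 360 with quantile normalization. The median shift was -0.229 at dose 0 and -0.291 at 100 ng/ml. The 1467 calls at dose 0 were 105 without unengaged number 1, 2 without unengaged number 2, 522 without engaged number 1 and 29 without engaged number 2. The sum at 10 ng/ml (77) was 3 and 5 without unengaged numbers 1 and 2 and 4 without engaged number 1, and that at 100 ng/ml (4003) 1479 without unengaged number 2 and 2324 without engaged number 1. That at 1000 ng/ml (2315) was 1101 and 852 without unengaged numbers 1 and 2 and 1096 and 1115 without engaged numbers 1 and 2. That at 10000 ng/ml (866) was 425 and 295 without unengaged numbers 1 and 3, and 344 and 261 without engaged numbers 2 and 3.

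The engagement effect under stimulation differed from that at dose 0 for 2 genes in CD4 cells, both lower, with 869 at an unadjusted p under 0.05. Both are near the floor at dose 0 without engagement (Ifng 0.0355 ± 0.0502 RPM, Ccl1 0.508 ± 0.393 RPM), where engagement could hardly lower them. Ifng differed by -1.60 (SE 0.25, adjusted p = 0.0172) and stood at 0.23 at dose 0 (adjusted p = 0.474). Ccl1 differed by -1.16 (SE 0.18, adjusted p = 0.0172) and stood at -0.25 at dose 0 (adjusted p = 0.263). EdgeR and a pseudocount of 0.1 called 0 genes and DESeq2 7, and the count was 1 without either unengaged dose 0 library, 4 without either engaged dose 0 library, without engaged 100 ng/ml number 1 or without engaged 10000 ng/ml number 1, and 5 without 10 ng/ml number 2.

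The half-maximal dose of the 959 genes at least 2-fold higher in CD4 cells had a median of 193 ng/ml (quartiles 152 and 253 ng/ml), and their median inhibition was 25.6% (quartiles 14.2 and 36.5%). In 3 groups of genes from the lowest to the highest half-maximal dose the median inhibition was 26.1, 24.9 and 26.3%. The Spearman correlation across genes was 0.06 for the summed inhibition, -0.06 with the dose read on log2 values, -0.04 without replicate number 2 and 0.317 at a log2 change of at least 2. At the top dose alone it was 0.39, with median inhibitions of 6.93, 10.5 and 23.6% in these groups. Of these genes 599 were called lower with engagement and 36 higher (319 and 90 with quantile normalization). Over all genes, 1553 rose with stimulation and fell with engagement (1157 for unrelated lists, and 713 and 417 with quantile normalization). The same kind of simulation gave 0, which cannot tell how far shared libraries raise that overlap, as in the hybridoma. Genes lower with stimulation and higher with engagement numbered 146 (184 for unrelated lists, and 571 and 494 with quantile normalization). A further 139 rose in both comparisons (126) and 1356 fell in both (1688).

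Both systems shared many genes of the TCR response. Among 9347 genes tested in both, 501 rose in both with stimulation (209 for unrelated calls, odds ratio 6.38, Fisher's exact p = 8.56e-121), including Egr2, Nr4a1, Ccl1, Il2 and Pdcd1, and 1337 fell in both (756, odds ratio 4.92, p = 1.29e-199). With quantile normalization these counts were 760 and 847, and rho of log2 differences across genes was 0.52 (0.44 with quantile normalization). With PD-1 engagement 63 genes fell in both (34.2 for unrelated calls, odds ratio 5.02, Fisher's exact p = 6.34e-11; 65 against 13.0 with quantile normalization), among them Egr2, Nr4a1, Ccl1 and Il2. No gene rose in both with engagement without pairs (0 against 0.225; 2 with quantile normalization). With pairs blocked in the hybridoma, 38 rose in both (8.31 for unrelated calls) and 323 fell in both (186), while 47 rose in the hybridoma and fell in CD4 cells. The Spearman correlation for the engagement differences was 0.30. Genes are not independent replicates, so the p-values of Fisher's exact test describe the overlap alone. Among genes of at least median abundance in both, 313 rose and 430 fell in both with stimulation (164 and 210 for unrelated calls). With engagement 32 of them fell in both (21.1). Doses of pOVA and 2C11 are of different reagents and were not matched.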

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

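Of the tests below, those on scaling and on transcript length, on noise shared by the measures of dose and inhibition, on the median difference between the dose 0 libraries and on that between 1000 and 1 nM were chosen after the result was seen, as were the fits with a B cell marker covariate and the simulations for clusters with no gene symbol.

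Ifng and Ccl1 stood out in CD4 cells by the tested difference between their engagement effects under stimulation and at dose 0, -1.60 (SE 0.25) and -1.16 (SE 0.18), adjusted p = 0.0172 for each. Their dose 0 levels without engagement were 0.0355 ± 0.0502 and 0.508 ± 0.393 RPM, so near the floor that engagement had almost nothing to lower there. A pseudocount of 0.1 and edgeR called 0 genes. The effects of stimulation also differed between systems. CD4 minus hybridoma log2 differences were 3.03 (SE 0.21, adjusted p = 1.13e-12) for Myc, 1.63 (SE 0.27) for Il2 and 0.54 (SE 0.21, adjusted p = 0.043) for Pdcd1, and -2.01 (SE 0.41) for Cd274, -1.42 (SE 0.30) for Nr4a1 and -0.96 (SE 0.37, adjusted p = 0.0387) for Egr2. Genes higher at the top dose in the hybridoma and lower in CD4 cells, with the difference called, numbered 72, and genes lower in the hybridoma and higher in CD4 cells 160. Opposite calls, without that test, were 117 and 160 with quantile normalization, and 22 and 7 when the hybridoma change was at least 2-fold.

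Clusters with no gene symbol, which were left out of the comparisons of genes, also changed with stimulation and engagement. In the hybridoma 551 of 4473 tested were at least 2-fold higher at the top dose than at dose 0, and 147 of these were lower with PD-1 engagement (18.1 for unrelated lists). In CD4 cells 483 of 3642 were at least 2-fold higher, and 91 of these were lower with engagement (34.9). The comparisons share unengaged libraries, and 20 simulations with the stimulation differences and no engagement effect gave 0 in either system. Hardly any cluster would be called with engagement in such simulations, so this cannot tell how far shared libraries raise the overlap. Over all clusters with no symbol, 105 in the hybridoma and 788 in CD4 cells were at least 2-fold lower at the top dose. With engagement 147 were lower and 6 higher in the hybridoma, and 263 lower and 585 higher in CD4 cells. In CD4 cells the whole class held a larger share of deposited tags with engagement (median 8.27% against 6.5% without), and deposited tags a smaller share of the library (83.8% against 85.9%), so library quality stays open for the 585. A hybridoma cluster on chromosome 15 (59973458 to 59973461, plus strand), picked after its values were seen, went from 1.04 ± 0.233 to 153 ± 14.8 RPM and stood at 113 ± 9.69 RPM with engagement. Another induced cluster lay close to it (59973635 to 59973726, plus strand). In CD4 cells an induced cluster on chromosome 4 (48060123 to 48060230, plus strand) lay near that of Nr4a3 (48058149 to 48058255). Such clusters are therefore not independent of each other or of the named genes.

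CD4 libraries with and without PD-1 engagement differed before any stimulation, with 78 genes higher and 1389 lower at dose 0. The fit with the B cell marker covariate called 3028 genes, 206% as many, among them all 78 higher and all 1389 lower genes. It does not decide on RNA of B cells in the engaged libraries. Its slope comes from differences within groups, where the markers of most groups were higher in number 2 than in number 1, so it partly follows replicate number. The 5 markers differed by a median log2 of 0.211 at dose 0, with none called. Of the higher genes 55.1% (43) kept the call with quantile normalization. This does not test scaling as their cause, since that normalization moved the median shift from -0.229 to -0.0118, in favour of higher calls. Of the lower genes 2.30% (32) kept the call. The same move of the median works against lower calls, so this cannot tell scaling to library totals from a broad fall. Scaling stays open for the lower genes. Across 9162 genes the difference went with transcript length (rho -0.45), beyond the largest value between unengaged libraries of 1 dose (0.271) and also at 10, 100 and 1000 ng/ml (-0.33, -0.45 and -0.36) but not at 10000 ng/ml (0.14). Averaged over stimulated doses it was -0.398, so a difference in RNA or library quality stays open there too. An effect of engagement at rest, which the design names, was not tested.

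In the hybridoma, genes with a higher half-maximal dose had more PD-1 inhibition (rho 0.51 over 234 genes). Against noise shared by the measures stands a rho of 0.376, the lower of the values with dose and inhibition taken from different libraries. Equal inhibition of every gene gave at most 0.129 in 100 simulated sets. Their noise was drawn apart for each gene and library. Noise that genes or paired libraries share was left out, so these sets do not exclude equal inhibition. Size of induction with abundance left a partial correlation of 0.499. A common shift of the dose scale by engagement may account for it. By construction such a shift takes more from genes with a higher half-maximal dose, so its rho is no test apart from the pattern itself. A 12.02-fold shift predicted the inhibition with a rho of 0.488, no higher than that of the half-maximal dose (0.51). Its median error was 10.7 percentage points, against 14.1 for equal inhibition. With split libraries the shifts were 10-fold and 7.59-fold and rho was 0.443 and 0.259 (errors 13.7 against 17.7, and 12.6 against 13.8). The second rho lies under the bound that had been set for the fit without a split. The same model in CD4 cells gave a rho of -0.10 and a larger median error than equal inhibition (12 against 11.27), so the hypothesis is stated for the hybridoma alone. In CD4 cells the correlation of dose and inhibition, 0.06, was 0.317 at a log2 change of at least 2 and 0.386 at the top dose alone, which leaves it open there.

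B cell markers were high in the dose 0 hybridoma libraries of number 2, where 17 of 18 markers were at least 2-fold above number 1, and 2095 genes were lower at the top dose. RNA of B-lineage cells, left in spite of the purification of T cells that the labels name, could lower genes in that comparison. Of the lower genes 50.9% were also lower against 1 nM (exact 95% interval 48.8 to 53.1), which alone leaves the matter undecided around the bound of 50. The median excess of number 2 over number 1, 0.0999 for the lower genes and 0.132 for genes not called, decides nothing, since a wide gap also widens the spread and hinders a call. Against it as the whole cause stands a median difference of -0.482 between 1000 and 1 nM over the lower genes (-0.504 to -0.455 in 200 resampled sets; -0.100 over all genes), from libraries outside the comparison with summed B cell markers of 13.1 to 29.9 RPM, against 250.8 RPM in number 2. Without the dose 0 libraries of number 2, 0 of the 10 named lower genes lost the call, which decides nothing, since the rule had taken genes with number 1 above all 3 top-dose libraries. A part in the count stays open, which was 980 without unengaged number 2 and 2396 without number 1, as it does for the 38 lower genes at least 2-fold higher in number 2.

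For PD-1 engagement averaged over doses, 1 of 100 splits of the libraries within pairs in the hybridoma and within doses in CD4 cells, the real one, called as many genes. The real counts were 94 and 4663, the highest other 85 and 3862, and the median other 1 and 0. Chance is thus unlikely to account for either count, though 100 splits cannot exclude it. In CD4 cells the splits cannot tell engagement from a difference in library quality between the groups. At the top dose, 1 of 10 splits, the real one, called as many (41 and 866, highest other 0 and 1), and 10 splits are too few for a share under 0.05.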

How the results depend on the processing

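The fits with edgeR and TMM factors, DESeq2, TMM-scaled values, pairs within dose, the B cell marker covariate, both dose 0 hybridoma libraries of number 2 left out and 1 nM as the baseline were chosen after seeing the data, as were quantile normalization for lists and overlaps and hybridoma pairs for overlaps. Of 476 alternative values for 25 results, 364 kept their direction and stayed close, 110 moved and 2 reversed. For 378 values of named genes, 9828 of 10337 alternatives gave the same call, 387 lost it, 121 gained it and 1 reversed. Where no reason is given below, the cause was not tested.

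A 2-fold minimum leaves fewer genes by construction. Hybridoma stimulation went from 817 higher and 2095 lower to 234 and 267, the lower doses from 3112 to 606, PD-1 averaged from 6 and 88 to 0 and 2, and PD-1 at any dose from 75 to 42. CD4 stimulation went from 2812 and 4101 to 959 and 1477, the lower doses from 6364 to 2123, PD-1 averaged from 458 and 4205 to 5 and 9, and PD-1 at any dose from 5116 to 471. Genes shared by both systems went from 501 higher, 1337 lower and 63 lower with PD-1 to 83, 137 and 1, and with genes of at least median abundance to 313, 430 and 32.

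Scaling changed the balance of higher and lower genes. Quantile normalization gave 1300 higher for hybridoma stimulation, 1440 and 1301 for CD4 PD-1 averaged, 2973 for CD4 PD-1 at any dose, and 760 and 847 shared genes. EdgeR with TMM, DESeq2 and TMM-scaled values gave 1357, 1479 and 1400 higher for hybridoma stimulation. For CD4 PD-1 they gave 1624, 1322 and 1569 higher, 1335, 1274 and 1326 lower, and 3321, 3024 and 3180 at any dose. DESeq2 gave 19 higher for hybridoma PD-1 averaged and 155 at any dose.

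With only the groups of the contrast, and so fewer libraries, hybridoma stimulation gave 386 and 699, its lower doses 246, and PD-1 17 higher averaged and 36 at any dose. A test per deposited cluster counts clusters, not genes: 2480 higher for hybridoma stimulation, 5512 at its lower doses, 18 and 309 for PD-1 averaged and 285 at any dose; and in CD4 cells 4531 and 6600, 10194, and 1241 higher for PD-1. Pairs gave 201 and 456 for hybridoma PD-1 averaged, 323 genes lower in both systems (63 without pairs), 1118 at any dose and 7 for the difference from dose 0 (0 without pairs). A pseudocount of 0.1 gave 40 for hybridoma PD-1 at any dose, and replicate number as a factor 10 higher averaged. The B cell marker covariate gave 21 higher averaged, 128 at any dose and 1 for the difference, and in CD4 cells turned Cd74 from 0.45 to -0.114 (adjusted p = 0.0928). With it 231 of the 458 higher and 3559 of the 4205 lower CD4 genes kept their averaged PD-1 call. Without both dose 0 libraries of number 2, hybridoma stimulation gave 1001 lower, 1617 at lower doses and 17 higher for PD-1, and with 1 nM as the baseline 1248 lower.

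The CD4 difference from dose 0, 2 genes, was 4 without trend, 0 and 6 with pseudocounts of 0.1 and 5, 0 with edgeR on library totals and 0 with TMM, 7 with DESeq2, 1 with TMM-scaled values, 4 with pairs and 6 with the B cell marker covariate.

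The Spearman correlation of half-maximal dose and inhibition in the hybridoma (0.512) was 0.478 on log2 values, 0.587 at the top dose alone, 0.468 and 0.376 with the measures from different replicate numbers, 0.592 at a log2 change of at least 2 and 0.44 without the dose 0 libraries of number 2. In CD4 cells (0.0552) it was -0.0616 on log2 values, 0.386 at the top dose alone and 0.317 at a log2 change of at least 2.

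Lists called went from 13 for hybridoma stimulation and 9 for PD-1 to 6 and 5 with an estimated correlation. In CD4 cells they went from 12 and 13 to 5 and 2, and to 20 and 20 with fry, which tests a list on its own.

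Leaving out 1 library at a time leaves some groups with 1, assumed to vary like the others. Hybridoma stimulation ranged from 598 to 760 higher and from 980 (without dose 0 number 2) to 2396 lower, with 1266 without 10000 nM number 3, and its lower doses from 1371 (without 1000 nM number 2) to 3529, with 1535 without dose 0 number 2. Hybridoma PD-1 averaged ranged from 3 (without 100 nM number 2, and without engaged 10 nM number 1) to 7 higher and from 64 to 103 lower. At any dose it ranged from 40 (without 100 nM number 1) to 92, with 46 without 100 nM number 2 and 49 without engaged 10000 nM number 2. The difference from dose 0 ranged from 0 to 3 (without dose 0 number 1), with 1 without engaged dose 0 number 2 and 1 without engaged 100 nM number 1. The Spearman correlation was 0.308 without number 2 and 0.337 without number 1. CD4 stimulation ranged from 2431 to 2778 higher, 3436 to 4046 lower and 5361 to 6312 at lower doses. CD4 PD-1 ranged from 365 to 504 higher, 3423 to 4470 lower and 3760 to 5509 at any dose. The CD4 difference ranged from 1 (without either unengaged dose 0 library) to 5 (without 10 ng/ml number 2), with 4 without either engaged dose 0 library, without engaged 100 ng/ml number 1 or without engaged 10000 ng/ml number 1. CD4 rho ranged from -0.0445 (without number 2) to 0.115.

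CD4 PD-1 with replicate number as a factor gave 530 higher and 4610 lower, and with pairs 494 and 4424. No cluster below 3.01 RPM in every hybridoma library was deposited, so the hybridoma depth of up to 19.7 M tags does not reach genes of lower abundance.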

Other observations

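Genes that moved in opposite directions with stimulation in the 2 systems include the following, picked after their values were seen from the 72 and 160 such genes. Lef1, a factor of naive T cells, rose by 1.24 in the hybridoma and stood at -2.05 in CD4 cells, Btg2, which restrains proliferation, at 0.76 and -2.32, and the costimulatory receptor Cd27 at 2.70 and -0.60. The transcription repressor Gfi1 stood at -0.76 in the hybridoma and 3.11 in CD4 cells, Dusp6 at -0.84 and 2.50, and Mcm2, part of the replication helicase, at -0.74 and 0.72.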
